A study of Mus musculus with 11 samples.

How the data were processed

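The series holds 11 Affymetrix arrays of 3T3-L1 adipocytes. Per the labels' protocols, preadipocytes were differentiated and then treated so that all cells were harvested the same number of days after differentiation. Insulin was given at 10 nM in 4 additions, TNF at 2 ng/ml for 4 days, and dexamethasone at 20 nM for 8 days with ethanol (0.01%) as the carrier. Biotin-labelled cRNA was made from 3 µg of total RNA. The protocol names the carrier as the control for dexamethasone, while the control arrays are labelled as untreated, so whether those cells received it is unclear. Groups and replicate numbers were taken from the sample titles.

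The authors deposited 1 table of linear intensity values, with 45101 probe sets and 1 column per array, and 0 value columns belonged to no sample. The method of background correction, summarisation and normalization is not given in the sources used here. The deposited intensities ran from 6.01 to 25900, and the quartiles of their log2 values differed by at most 0.0763 between arrays. As this was under the limit of 0.1 set for further normalization, none was applied. Within groups the Spearman correlation of arrays was 0.9961 to 0.9977, and 9 to 30 probe sets per pair had identical values, so that no array was a copy of another. The ratio of the 3' to the 5' control probe sets was 1.04 to 1.11 for Gapdh and 1.43 to 1.82 for actin, with the highest actin ratio in CI replicate 1 and the lowest in CI replicate 2. All 18 hybridization spike probe sets were lower in CI than in control (median -0.23, unadjusted p from 0.0502 to 0.178). Smaller shifts the same way were seen for 18 in TNF (median -0.07) and 17 in DEX (median -0.05). The 3' BioB probe set, for example, lay at 341.8 and 283.0 in CI against 364.8 to 396.6 in control, and at 306.9 in TNF replicate 3 and 339.5 in DEX replicate 2. The 3' probe set of the Dap spike was at 512.8 in DEX replicate 2 and at 101.0 to 157.5 in the other arrays.

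Values were transformed as log2(intensity + 16), so fold changes are on that scale and understate the change of dim genes. The 64 Affymetrix control probe sets were left out. In the platform annotation given for this work, 34945 probe sets had 1 gene symbol, 932 had several and 9160 were not listed with a gene. Of those with 1 symbol, 34741 were matched by gene identifier, and 0 symbols changed. No gene was named from a probe set with several symbols. For each of 18193 genes the probe set with the highest mean over all arrays was used. For 9010 genes there was more than 1. Genes with a mean under the 25th percentile of all probe sets (an intensity of 51.6) were left out, which left 15625. Pdss1 was not analysed here.

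Each comparison was tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes, two-sided) on all 11 arrays with a mean per group, so that the groups shared an estimate of the spread (7 residual and 7.62 prior degrees of freedom). Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all 15625 genes. Each treatment was compared with control and with the other treatments. Errors beside intensities are SDs between arrays, and errors beside log2 fold changes are standard errors of the fit.

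The groups, tests, alternatives, the rule for named genes and 21 gene lists were fixed before the data were examined. The lists had 628 entries of 600 distinct symbols, and 570 entries were tested. They covered adipocyte genes, insulin signalling, FOXO targets, cholesterol synthesis, coenzyme Q synthesis, fatty acid and triglyceride synthesis, oxidative phosphorylation, the tricarboxylic acid cycle, branched-chain amino acid catabolism, fatty acid oxidation, TNF and NF-kappaB targets, interferon response and MHC class I, glucocorticoid receptor targets, extracellular matrix, cell cycle, endoplasmic reticulum stress, antioxidant genes, glycolysis and hypoxia, and markers of preadipocytes and fibroblasts, of macrophages and leukocytes, and of brown adipocytes. A list was compared with all other tested genes by camera with a preset correlation of 0.01, adjusted over the 21 lists. Camera with a correlation estimated from the data, and fry, were run as alternatives. Members were also counted after adjustment over the list alone.

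The text names, for each comparison with control, the 8 highest and 8 lowest log2 fold changes among genes that passed with every treated array beyond every control array, up to 4 members of a list with the smallest adjusted p, the 5 highest and 5 lowest between treatments, the 8 in each direction that passed in all 3 with the largest smallest change, and 14 genes named in advance. Where a few examples of a list served, its other members are given as counts.

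Overlaps between comparisons that share the control arrays were set beside 100 simulations of unchanged groups and beside the overlap of independent lists. In each simulation the deviations of arrays from their group means were drawn with replacement and random signs for all groups, controls included. A simulated group could thus hold copies of a single array's deviation. The alternatives were centring, quantile normalization, other dim filters, the mean of all probe sets of a gene, offsets of 1 and 64, eBayes with trend and robust, only the 2 groups compared, the replicate number as a block, and leaving out each array.

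The test was tried on simulated data with 50 genes changed at each of 4 sizes in 15625 genes. For CI against control 52% of the 1.25-fold, 82% of the 1.5-fold and 100% of the 2-fold changes were recovered, for TNF 64%, 94% and 100%, and for DEX 82%, 100% and 98%. The share of false calls was 5.11%, 1.10% and 4.04%. Between treatments 70%, 54% and 52% of the 1.25-fold changes were recovered for TNF against DEX, TNF against CI and DEX against CI. The simulated noise was drawn for each gene independently, and few genes were changed. In the real data genes vary together, with an estimated correlation of up to 0.495 within a list. The shares recovered and falsely called may thus not hold for the real calls.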

Results

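Gene expression was measured on Affymetrix arrays in 3T3-L1 adipocytes, a mouse cell line that is differentiated from preadipocytes in culture. The 11 arrays fell into 4 groups: untreated control (n = 3), chronic insulin (CI, n = 2), tumour necrosis factor (TNF, n = 3) and dexamethasone (DEX, n = 3). Dexamethasone is a synthetic glucocorticoid, and TNF is an inflammatory cytokine. The labels present all 3 treatments as ways of making the adipocytes insulin resistant. Each array held 45101 probe sets with a median intensity of 124.5 to 129.5, and the number of arrays limits the precision of every value. After log2 transformation and a filter on dim genes, 15625 genes were tested. The labels call the arrays of a group experimental replicates and do not say that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Principal components 1, 2 and 3 held 48.1%, 32.1% and 7.68% of the variance. The DEX arrays stood apart on component 1, the TNF and CI arrays lay at opposite ends of component 2, and the control arrays stood apart on component 3.

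Chronic insulin against control asked what repeated insulin additions changed in the adipocytes. Dusp6 and Dusp4, phosphatases that inactivate ERK kinases, rose with log2 fold changes of 1.66 (SE 0.174) and 1.57 (SE 0.105). The intensity of Dusp6 was 639.2 ± 45.4 (SD, n = 2) against 191.1 ± 12.4 (SD, n = 3) in control. Angptl8, a secreted regulator of lipoprotein lipase, rose by 1.27 (SE 0.0726), from 151.8 ± 11.7 to 388.5 ± 3.81, and Cth, an enzyme of cysteine synthesis, rose by 1.29 (SE 0.0904), from 592.2 ± 40.6 to 1470 ± 140. Lcn2 (1.69, SE 0.324), Tmigd1 (1.42), the chemokine Cxcl10 (1.21) and Pla2g2e (1.17) were the other genes of the 8 largest increases. The largest decreases were those of Agmo (-1.42), Cirbp (-1.13), Ccl9 (-1.13) and the sulfotransferase Sult1a1 (-1.09, from 4417 ± 82.3 to 2063 ± 188), then Nat8f3 (-1.03), Phkg1 (-1.01), Smim5 (from 396.9 ± 7.64 to 190.2 ± 9.39) and Nudt18 (-0.96). Their adjusted p-values (limma, Benjamini-Hochberg) ran from 2.55e-07 for Angptl8 to 0.00229 for Lcn2.

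In total 2692 genes passed in the CI comparison, 1308 higher and 1384 lower, of which 18 were higher and 8 lower by more than 2-fold. In 2691 of them every CI array lay beyond every control array. Such separation held for 46.0% of all tested genes, where chance gives 20%. The split moved with single arrays. Without CI replicate 1 it was 555 higher and 876 lower (1431 genes), without CI replicate 2 it was 1024 and 862, without control replicate 1 it was 975 and 966, and without control replicate 2 it was 851 and 1079. Where 1 CI sample is left, it is assumed to vary like the other groups.

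Glycolysis and hypoxia genes rose in CI. Of 22 tested, 15 rose and 2 fell, or 15 and 3 adjusted over the list alone, with a median log2 fold change of 0.41 (camera, adjusted p = 6.09e-09, and adjusted p = 0.109 with an estimated correlation). Pkm, Ldha, Pfkp and Pfkl, all enzymes of glycolysis, rose by 0.80, 0.76, 0.74 and 0.61. The intensity of Ldha went from 4183 ± 193 to 7076 ± 396. Of 27 endoplasmic reticulum stress genes 11 rose and none fell (11 and 0 adjusted over the list alone, median 0.23, adjusted p = 6.7e-06, and adjusted p = 0.109 with an estimated correlation). Among them were Edem1 (0.44) and the chaperone Hspa5 (0.33, from 7858 ± 270 to 9845 ± 197). Of 34 interferon and MHC class I genes 10 rose and 0 fell (11 and 0 adjusted over the list alone, median 0.19, adjusted p = 0.000688, and adjusted p = 0.935 with an estimated correlation), with Cxcl10, Rsad2 (0.68), Oas1a (0.49) and Ddx58 (0.48) among the increases.

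Genes of branched-chain amino acid catabolism fell in CI. Of 25 tested, 12 fell and 2 rose (14 and 3 adjusted over the list alone, median -0.20, adjusted p = 1.9e-05, and adjusted p = 0.677 with an estimated correlation), among them Bckdha (-0.57), Aldh6a1 (-0.51) and Bckdk (-0.45), which encodes the kinase that inhibits the branched-chain ketoacid dehydrogenase. Of 18 preadipocyte and fibroblast markers 7 fell and 0 rose (9 and 0 adjusted over the list alone, median -0.19, adjusted p = 4.69e-05, and adjusted p = 0.109 with an estimated correlation), including Acta2 (-0.63), Dlk1 (-0.56) and S100a4 (-0.47).

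The other 16 lists did not pass in CI (adjusted p from 0.168 to 0.876). Of 28 adipocyte genes 6 rose and 5 fell: G0s2, an inhibitor of the lipase encoded by Pnpla2, rose by 1.02, while Pnpla2 (-0.57) and Car3 (-0.68) fell. Of 32 insulin signalling and glucose uptake genes 5 rose and 6 fell, or 6 and 8 adjusted over the list alone. Grb14, an adaptor that inhibits the insulin receptor, rose by 0.69, and Igf1r fell by 0.38. Of 71 oxidative phosphorylation genes 7 rose and 4 fell. Among 14 macrophage and leukocyte markers Mpeg1 rose (0.57) while Cd14 (-0.68) and Lyz2 (-0.64) fell. Without CI replicate 2, 8 lists passed instead of 5.

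Insr fell in CI by 0.42 (adjusted p = 0.000681) on its brightest probe set, but its mean over all probe sets did not pass (-0.07, adjusted p = 0.396). Irs1 fell by 0.30 (adjusted p = 0.0109) and Srebf1 by 0.33 (adjusted p = 0.00691), and neither passed without CI replicate 2 (adjusted p = 0.102 and 0.130). Irs2 was at -0.19 (adjusted p = 0.0299) and did not pass without control replicate 1 (0.0709), control replicate 3 (0.0892), CI replicate 1 (0.125) or CI replicate 2 (0.127). Adipoq (-0.08), Pparg (-0.01), Slc2a4 (-0.12), Fkbp5 (-0.08), Tsc22d3 (-0.26), Ccl2 (0.30), Saa3 (0.05), Hmgcs1 (-0.11) and Coq7 (0.23) did not pass. Adipoq lay at 20820 to 23390 on the arrays of all groups, whose highest values were 22500 to 25930. A change of Adipoq in any treatment may thus be compressed. The median, the mean and the list test differed in sign in CI for fatty acid oxidation, glucocorticoid receptor targets, antioxidant genes and macrophage markers, none of which passed.

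**Figure D1:**
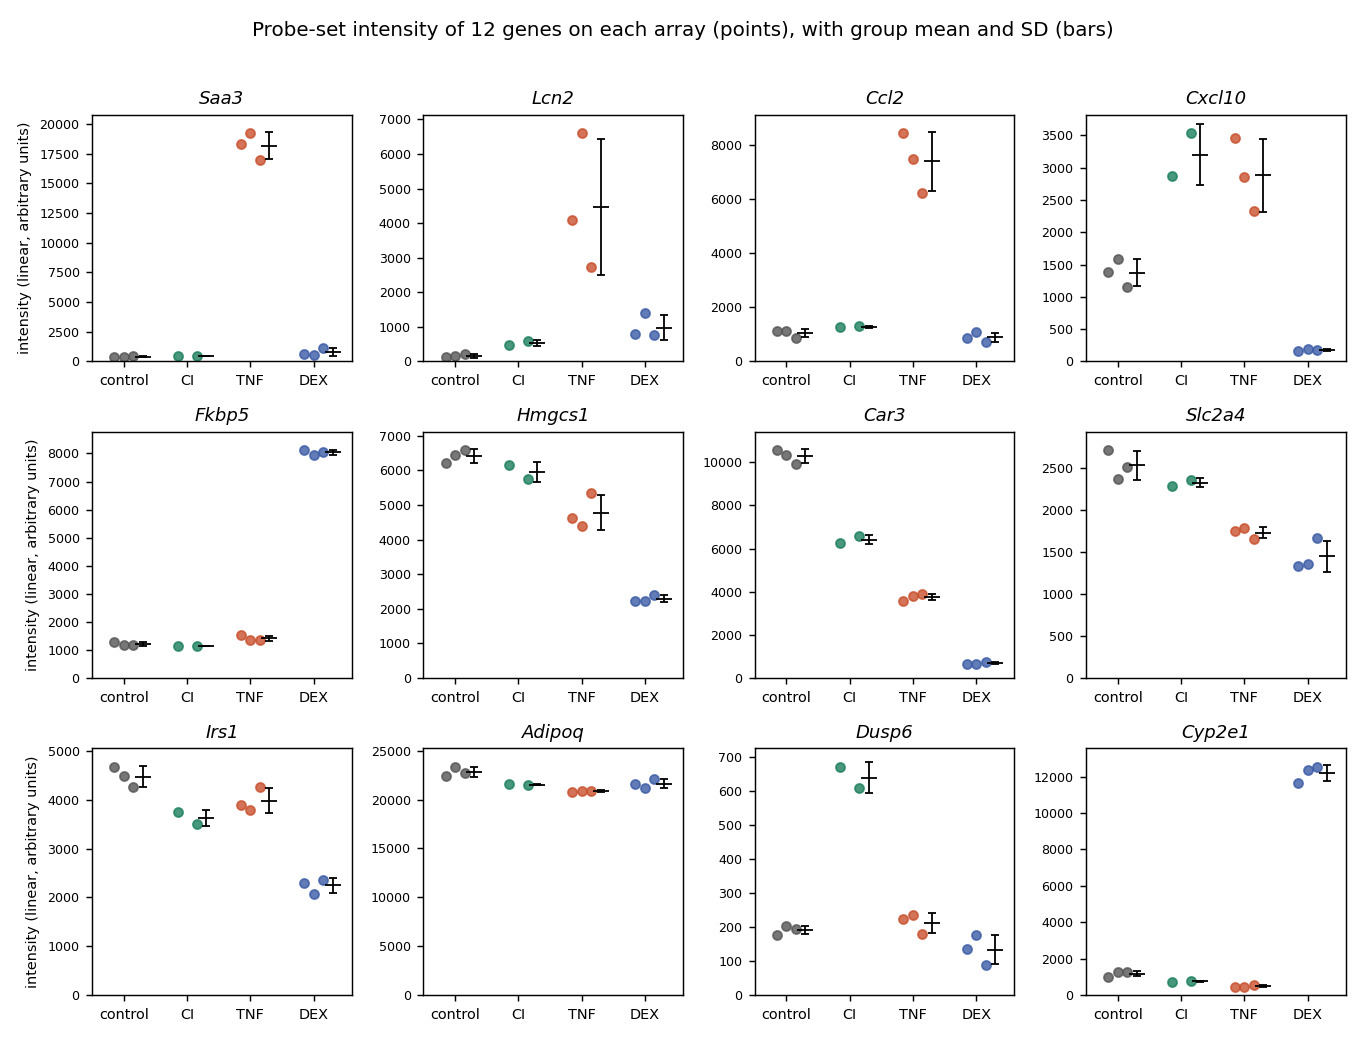
Probe-set intensity (linear, arbitrary units) of 12 genes on each of the 11 arrays, with points for arrays and bars for the group mean and SD. Saa3 reached 18180 in TNF against 399.4 in control, Fkbp5 reached 8045 in DEX against 1214, and Dusp6 reached 639.2 in CI against 191.1.

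TNF against control asked what exposure to a low dose of the cytokine changed. Saa3, an acute-phase serum amyloid gene, rose from an intensity of 399.4 ± 50.4 (SD, n = 3) to 18180 ± 1130 (SD, n = 3), a log2 fold change of 5.46 (SE 0.176). Lcn2, which encodes an iron-siderophore binding protein, rose by 4.63 (SE 0.289), from 159.5 ± 58.8 to 4471 ± 1970. The chemokine genes Ccl5 (3.58), Cxcl11 (3.13) and Ccl8 (3.07) rose as well, with Ccl5 going from 542.7 ± 36.8 to 6660 ± 480, and so did Hpx (3.49), which encodes a haem-binding plasma protein, complement factor gene Cfb (3.15) and Chil1 (2.86). Lrrc17 (-1.56), Car3 (-1.45, from 10270 ± 325 to 3749 ± 150), Poln (-1.35), Thrsp (-1.35), Gpat3 (-1.31), Cyp2e1 (-1.28), Pck1 (-1.21) and Pygl (-1.21) fell. The adjusted p-values of these genes (limma, Benjamini-Hochberg) ran from 1.48e-12 for Cxcl11 to 0.000231 for Pck1.

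In total 3924 genes passed in TNF, 2169 higher and 1755 lower. Which direction held more genes turned with the scaling: 2388 were higher and 1384 lower after centring, and 1783 and 2074 after quantile normalization. More than 2-fold changes were 117 increases and 14 decreases. In 3849 of the 3924 genes every TNF array lay beyond every control array, and such separation held for 43.1% of all tested genes, where chance gives 10%.

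Of 34 TNF and NF-kappaB target genes 28 rose and 0 fell (29 and 0 adjusted over the list alone, median 1.03, adjusted p = 5.99e-26, and adjusted p = 0.088 with an estimated correlation). Ccl2, a monocyte chemokine, rose by 2.82 (SE 0.134), from 1036 ± 143 to 7401 ± 1100, and the receptor gene Tlr2 rose by 2.19. Of 31 cell cycle genes 22 rose and 0 fell (24 and 0 adjusted over the list alone, median 0.29, adjusted p = 6.28e-12, and adjusted p = 0.088 with an estimated correlation), including Ccnd1 (0.82), Rrm2 (0.65), Top2a (0.64) and Cdk1 (0.55). Of 34 interferon and MHC class I genes 13 rose and 2 fell (13 and 3 adjusted over the list alone, median 0.09, adjusted p = 0.00744, and adjusted p = 0.541 with an estimated correlation), with Cxcl10 (1.05), Ifit2 (0.84) and Psmb10 (0.53) among the increases.

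Genes of mitochondrial metabolism fell in TNF. Of 71 oxidative phosphorylation genes 55 fell and 0 rose (59 and 0 adjusted over the list alone, median -0.23, adjusted p = 1.99e-18, and adjusted p = 0.113 with an estimated correlation), among them Ndufs1 (-0.54), Uqcrfs1 (-0.47) and Cycs (-0.35). Of 23 tricarboxylic acid cycle genes 21 fell and 0 rose (21 and 0 adjusted over the list alone, median -0.35, adjusted p = 1.82e-15, and adjusted p = 0.088 with an estimated correlation), and Pdhb, a subunit of pyruvate dehydrogenase, fell by 0.78. Of 25 branched-chain amino acid genes 22 fell and 1 rose (23 and 1 adjusted over the list alone, median -0.44, adjusted p = 1.82e-15, and adjusted p = 0.088 with an estimated correlation). Ivd (-0.66) and Mccc1 (-0.65) were among those that fell, and Bcat1 (0.62) was the gene that rose. Of 20 fatty acid oxidation genes 14 fell and 0 rose (16 and 1 adjusted over the list alone, median -0.25, adjusted p = 1.38e-07, and adjusted p = 0.088 with an estimated correlation), including Cpt2 (-0.63) and Acadvl (-0.57). Of 12 coenzyme Q synthesis genes 10 fell and 0 rose (10 and 0 adjusted over the list alone, median -0.28, adjusted p = 5.37e-05, and adjusted p = 0.113 with an estimated correlation), including Coq7 (-0.55, SE 0.0951) and Coq9 (-0.39). In the same arrays 7 of 18 preadipocyte and fibroblast markers rose and 1 fell (8 and 3 adjusted over the list alone, median 0.09, adjusted p = 0.00955, and adjusted p = 0.145 with an estimated correlation), including Ccn5 (1.01), Acta2 (0.94), S100a4 (0.79) and Pdgfrb (0.61).

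Genes of lipid storage and synthesis also fell in TNF. Of 28 adipocyte genes 17 fell and 1 rose (19 and 1 adjusted over the list alone, median -0.43, adjusted p = 9.48e-12, and adjusted p = 0.088 with an estimated correlation), with Car3, Tmem120a (-0.85), Retn (-0.83) and Dgat2 (-0.81) among the decreases. Of 24 fatty acid and triglyceride synthesis genes 17 fell and 1 rose (18 and 1 adjusted over the list alone, median -0.37, adjusted p = 2.57e-10, and adjusted p = 0.088 with an estimated correlation), including Lpin1 (-0.78) and Me1 (-0.75). Of 21 cholesterol and mevalonate synthesis genes 17 fell and 0 rose (18 and 0 adjusted over the list alone, median -0.50, adjusted p = 4.16e-12, and adjusted p = 0.113 with an estimated correlation), including Idi1 (-0.72), Fdps (-0.71) and Hmgcs1 (-0.43, from 6408 ± 193 to 4779 ± 502). Of 15 brown adipocyte markers 6 fell and 0 rose (11 and 0 adjusted over the list alone, median -0.19, adjusted p = 0.000151, and adjusted p = 0.088 with an estimated correlation), including Ebf2 (-0.45) and Esrra (-0.40).

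Of 38 extracellular matrix genes 15 rose and 6 fell in TNF (16 and 6 adjusted over the list alone, median 0.08, adjusted p = 0.0220, and adjusted p = 0.479 with an estimated correlation), with Timp1 (1.78), P4ha2 (1.07) and Fn1 (0.86) among the increases. This list did not pass with the dim filter at the median (adjusted p = 0.125) or with the mean of all probe sets (0.0734). Of 14 macrophage and leukocyte markers 4 rose and 2 fell (4 and 3 adjusted over the list alone, median 0.10, adjusted p = 0.0462, and adjusted p = 0.113 with an estimated correlation), including Cd74 (1.91), Cd14 (1.48) and Cd53 (0.61). It did not pass without DEX replicate 2 (adjusted p = 0.0631) or without the dim filter (0.0782).

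The other 6 lists did not pass in TNF (adjusted p from 0.097 to 0.924). Of 32 insulin signalling and glucose uptake genes 5 rose and 5 fell, the same numbers as adjusted over the list alone. Slc2a4, the insulin-responsive glucose transporter, fell by 0.54 (SE 0.0785, adjusted p = 0.000121), from 2539 ± 172 to 1734 ± 67.5, while Grb14 (1.27), Socs3 (1.07) and Igf1r (0.61) rose. Of 27 antioxidant genes 7 rose and 8 fell (8 and 11 adjusted over the list alone), with Mt2 (1.10) and Nqo1 (0.91) higher and Prdx3 (-0.53) lower. Of 20 FOXO targets 4 rose and 5 fell, with Igfbp3 (1.74) higher. Of 22 glycolysis and hypoxia genes 9 rose and 3 fell, with Adm (1.30) higher and Pfkfb3 (-0.76) lower. Srebf1 rose by 0.28 (adjusted p = 0.00705). Fkbp5 rose by 0.22 (adjusted p = 0.0133) and did not pass without control replicate 2 (0.0611), control replicate 3 (0.0548) or TNF replicate 1 (0.0740). Adipoq (-0.13), Pparg (-0.11), Insr (0.12), Irs1 (-0.17), Irs2 (0.01) and Tsc22d3 (-0.21) did not pass. The median was below 0 and the mean above 0 for glucocorticoid receptor targets (-0.04 and 0.33) and antioxidant genes (-0.09 and 0.02).

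DEX against control asked what prolonged glucocorticoid exposure changed. Fam107a rose from an intensity of 112.6 ± 17.0 (SD, n = 3) to 5941 ± 326 (SD, n = 3), a log2 fold change of 5.54 (SE 0.105). The other large increases were those of the apolipoprotein gene Apoc3 (4.87), the carboxypeptidase gene Cpm (4.85), the retinaldehyde dehydrogenase gene Aldh1a1 (4.21), the cytochrome P450 gene Cyp2e1 (3.39, from 1156 ± 142 to 12210 ± 464), the prostaglandin D synthase gene Ptgds (3.38), Gsta3 (3.31) and Ccl6 (2.86). Car3, a carbonic anhydrase gene, fell by 3.87 (SE 0.0634), from 10270 ± 325 to 689.3 ± 59.4. The antiviral gene Rsad2 fell by 3.07 (SE 0.0859), from 3848 ± 162 to 445.7 ± 62.5, and Lum (-2.96), Cxcl10 (-2.90), Cxcl5 (-2.75), Cmpk2 (-2.71), Dpt (-2.65) and Iigp1 (-2.56) fell as well. The adjusted p-values of these genes (limma, Benjamini-Hochberg) ran from 1.19e-15 for Apoc3 to 1.73e-08 for Cxcl5.

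In total 4310 genes passed in DEX, 2186 higher and 2124 lower, against 2008 and 2154 after centring and 2188 and 2220 after quantile normalization. The lower genes were also the more numerous with only the 2 groups compared (1924 and 2007) and without control replicate 2 (1681 and 1780), control replicate 3 (1793 and 1843), TNF replicate 1 (2074 and 2078), TNF replicate 2 (2050 and 2051) or DEX replicate 2 (1815 and 2108). More than 2-fold changes were 105 increases and 173 decreases. In 4186 of the 4310 genes every DEX array lay beyond every control array, and such separation held for 40.5% of all tested genes, where chance gives 10%. The protocol names an ethanol carrier as the control for dexamethasone, while the control arrays are labelled as untreated, so whether those cells received the carrier is unclear.

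Of 34 interferon and MHC class I genes 33 fell and 0 rose in DEX (33 and 0 adjusted over the list alone, median -1.41, adjusted p = 2.6e-34, and adjusted p = 0.0561 with an estimated correlation). Besides Rsad2 and Iigp1, Oas1a fell by 2.03 and the immunoproteasome gene Psmb9 by 1.76. Among 14 macrophage and leukocyte markers in the same arrays Mpeg1 (-1.67), Itgb2 (-0.96) and Lyz2 (-0.62) fell and Cd14 rose (0.90). The list did not pass by camera (median -0.06, adjusted p = 0.230), but it passed as lower by fry (adjusted p = 0.000445). Of 34 TNF and NF-kappaB targets 9 rose and 8 fell (10 and 8 adjusted over the list alone, adjusted p = 0.392), with Tnfaip6 (-2.02) and Mmp3 (-1.16) lower and Saa3 (0.87) higher. Saa3 is also in the list of glucocorticoid receptor targets.

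Of 34 glucocorticoid receptor target genes 26 rose and 7 fell (26 and 7 adjusted over the list alone, median 0.88, adjusted p = 3.99e-11, and adjusted p = 0.0561 with an estimated correlation). Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 2.71 (SE 0.0579), from 1214 ± 59.5 to 8045 ± 83.1. Tsc22d3 rose by 1.99, from 994.2 ± 123 to 4000 ± 371, Errfi1 by 2.38 and Agt, which encodes angiotensinogen, by 1.59. Of 20 FOXO targets 12 rose and 4 fell (13 and 4 adjusted over the list alone, median 0.35, adjusted p = 0.00710, and adjusted p = 0.161 with an estimated correlation). Pdk4, which encodes an inhibitor of pyruvate dehydrogenase, rose by 2.70 and Txnip by 1.11, while Pck1 (-2.31) and Sesn3 (-0.85) fell. The FOXO and glucocorticoid receptor lists share 2 members, Pdk4 among them, so they are not separate for those genes.

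Cholesterol and mevalonate synthesis genes fell in DEX: of 21 tested, 20 fell and 0 rose (20 and 0 adjusted over the list alone, median -1.43, adjusted p = 3.33e-27, and adjusted p = 0.0561 with an estimated correlation). Hmgcs1 fell by 1.48 (SE 0.0696), from 6408 ± 193 to 2293 ± 97.7, and Tm7sf2 (-1.95), Sqle (-1.72) and Fdps (-1.66) fell as well. Of 24 fatty acid and triglyceride synthesis genes 17 fell and 2 rose (17 and 2 adjusted over the list alone, median -0.41, adjusted p = 5.82e-08, and adjusted p = 0.161 with an estimated correlation), including Acss2 (-1.53), Acly (-1.15) and Scd2 (-0.82), while Srebf1, whose product activates lipogenic genes, rose by 0.41. Of 28 adipocyte genes 16 fell and 4 rose (16 and 4 adjusted over the list alone, median -0.29, adjusted p = 2.11e-06, and adjusted p = 0.161 with an estimated correlation), including G0s2 (-1.47), Tmem120a (-1.23) and the glycerol channel gene Aqp7 (-0.98). Pparg, the nuclear receptor that drives adipocyte differentiation, fell by 0.39 (adjusted p = 0.000294). Adipoq, which lay near the top of the intensity scale, did not pass (-0.08, adjusted p = 0.265).

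Of 38 extracellular matrix genes 24 fell and 4 rose in DEX (24 and 4 adjusted over the list alone, median -0.36, adjusted p = 1.29e-08, and adjusted p = 0.161 with an estimated correlation), including Lum, Timp3 (-1.56), Col5a2 (-1.28) and Col3a1 (-1.19). Of 31 cell cycle genes 11 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.15, adjusted p = 0.000720, and adjusted p = 0.495 with an estimated correlation), including Rrm2 (0.80) and Ccnd1 (0.59). Of 18 preadipocyte and fibroblast markers, a list that did not pass, 4 rose and 4 fell, with Dlk1 (from 9889 ± 1280 to 4943 ± 552) and Pdgfrb (-0.91) lower and Klf2 (0.93) higher.

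The other 13 lists did not pass in DEX (adjusted p from 0.0507 to 0.994). Of 32 insulin signalling and glucose uptake genes 9 rose and 9 fell, or 9 and 10 adjusted over the list alone. Irs1 fell by 0.99 (SE 0.0664, adjusted p = 2.41e-08), from 4479 ± 211 to 2246 ± 156, and Slc2a4 fell by 0.80 (SE 0.0785, adjusted p = 1.55e-06), from 2539 ± 172 to 1454 ± 186. Irs2 rose by 0.42 and Tbc1d4, which encodes a substrate of AKT that controls glucose transporter traffic, by 0.86. Of 20 fatty acid oxidation genes 9 rose and 2 fell (adjusted p = 0.0507), including Ech1 (0.70) and Acadm (0.51). Of 71 oxidative phosphorylation genes 10 rose and 2 fell, or 2 and 1 adjusted over the list alone. Of 27 antioxidant genes 9 rose and 4 fell, with Gsta3, Mt2 (2.06) and Mt1 (0.98) among the increases. Mt1 and Mt2 are also in the glucocorticoid receptor list. Insr was at 0.18 (adjusted p = 0.0362), which ended with the mean of all probe sets (0.528), with centring (0.0525) and without control replicate 2 (0.149), control replicate 3 (0.0677) or DEX replicates 1, 2 or 3 (0.0516, 0.0562 and 0.117). Ccl2 (-0.23) and Coq7 (-0.17) did not pass. The median, the mean and the list test differed in sign for endoplasmic reticulum stress, glycolysis and hypoxia, and preadipocyte markers.

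**Figure D2:**
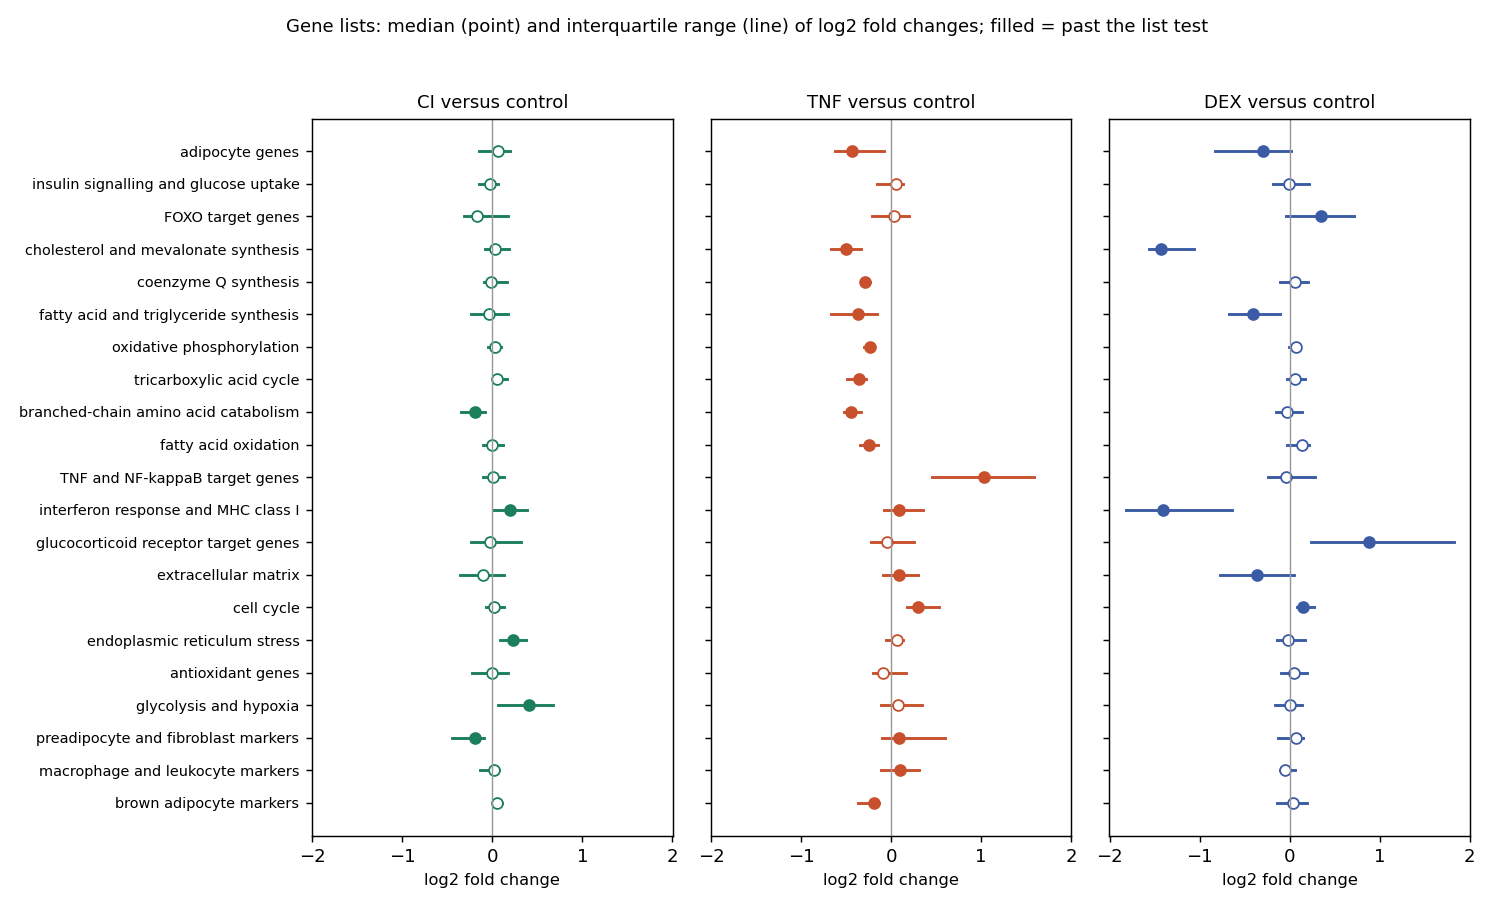
Median (point) and interquartile range (line) of the log2 fold changes of 21 gene lists in each treatment against control, with filled points for lists past the list test with a preset correlation. The TNF and NF-kappaB targets had a median of 1.03 in TNF, and the interferon and the cholesterol lists had medians of -1.41 and -1.43 in DEX.

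With the preset correlation 5 lists passed in CI, 15 in TNF and 8 in DEX, and with an estimated correlation 0 passed in each. At an unadjusted p under 0.05 the estimated correlation gave 3, 9 and 5 lists. By fry, which tests whether the genes of a list move one way on balance without comparing them with other genes, 4, 16 and 12 lists passed.

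TNF against DEX tested whether the cytokine and the glucocorticoid differed from each other. Cxcl5 was higher in TNF by 5.55 (SE 0.178), at 3850 ± 989 against 65.26 ± 12.9 (SD, n = 3 each), and Saa3 (4.58), Cfb (4.39), Ccl5 (4.17) and Hpx (4.08) were higher as well. Fam107a (-5.61), Apoc3 (-5.20), Cpm (-4.83), Cyp2e1 (-4.67) and Gsta3 (-3.57) were lower in TNF. All 34 interferon and MHC class I genes were higher in TNF than in DEX, also adjusted over the list alone (median 1.48, adjusted p = 1.75e-32, and adjusted p = 0.0711 with an estimated correlation). Of 71 oxidative phosphorylation genes 62 were lower and 1 higher (65 and 1 adjusted over the list alone, median -0.28, adjusted p = 6.26e-16, and adjusted p = 0.161 with an estimated correlation). Of 21 cholesterol synthesis genes 19 were higher and 0 lower (19 and 0 adjusted over the list alone, median 0.85, adjusted p = 3.71e-16, and adjusted p = 0.0711 with an estimated correlation). In all, 5636 genes differed, 2832 higher and 2804 lower in TNF. After centring 3103 were higher and 2097 lower, and after quantile normalization 2537 and 3098. The lower genes were also the more numerous without the dim filter (2873 and 2932), with the mean of all probe sets (2615 and 2899), with an offset of 1 (2790 and 2840) and without control replicate 1 (2824 and 2841). In this comparison 15 lists passed with the preset correlation and 0 with an estimated one.

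TNF against CI compared the cytokine with insulin. Saa3 (5.41, SE 0.197), Ccl5 (3.94), Ccl9 (3.87), Cfb (3.65) and Cxcl5 (3.25) were higher in TNF, and Angptl8 (-2.01, at 84.65 ± 3.93 with n = 3 against 388.5 ± 3.81 with n = 2), Gpat3 (-1.95), Dusp4 (-1.85), Pck1 (-1.83) and Pla2g2e (-1.63) were lower. Of 23 tricarboxylic acid cycle genes 20 were lower and 1 higher in TNF (20 and 1 adjusted over the list alone, median -0.46, adjusted p = 3.86e-10, and adjusted p = 0.220 with an estimated correlation). Of 22 glycolysis and hypoxia genes 11 were lower and 3 higher (13 and 4 adjusted over the list alone, median -0.22, adjusted p = 0.00246, and adjusted p = 0.220 with an estimated correlation). The interferon list did not pass (8 higher and 11 lower of 34, adjusted p = 0.864). In all, 5651 genes differed, 2942 higher and 2709 lower in TNF. After centring 3285 were higher and 2107 lower, and after quantile normalization 2619 and 2880. Without CI replicate 1 the split was 2444 and 1724, where the lone CI sample is assumed to vary like the other groups. In this comparison 15 lists passed with the preset correlation and 0 with an estimated one.

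DEX against CI compared the glucocorticoid with insulin. Fam107a (5941 ± 326 against 76.83 ± 5.24), Apoc3 (5.07), Cpm (4.95), Aldh1a1 (4.38) and Cyp2e1 (4.02) were higher in DEX. Cxcl10 was lower by a log2 difference of -4.11 (SE 0.146), at 169.7 ± 14.2 (SD, n = 3) against 3204 ± 469 (SD, n = 2), and Rsad2 (-3.75), Zbp1 (-3.27), Car3 (-3.19) and Pck1 (-2.94) were lower as well. Of 21 cholesterol synthesis genes 20 were lower and 0 higher in DEX (20 and 0 adjusted over the list alone, median -1.37, adjusted p = 3.67e-20, and adjusted p = 0.114 with an estimated correlation). Of 22 glycolysis and hypoxia genes 15 were lower and 3 higher (15 and 4 adjusted over the list alone, median -0.44, adjusted p = 4.55e-05, and adjusted p = 0.195 with an estimated correlation). In all, 5302 genes differed, 2663 higher and 2639 lower in DEX. The lower genes were the more numerous with only the 2 groups compared (2337 and 2349) and without CI replicate 2 (2013 and 2290, with the lone CI sample assumed to vary like the other groups) or DEX replicate 2 (2462 and 2740). In this comparison 12 lists passed with the preset correlation and 0 with an estimated one.

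**Figure D3:**
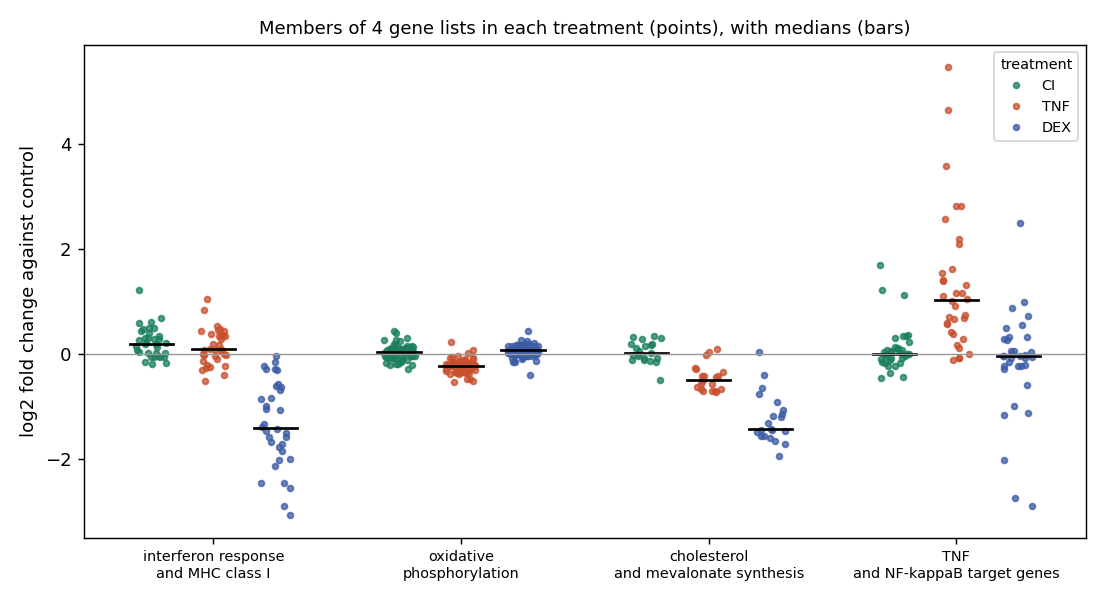
Log2 fold changes against control of the members (points) of 4 gene lists in CI, TNF and DEX, with bars for the medians. The interferon list had medians of 0.19, 0.09 and -1.41, and oxidative phosphorylation had medians of 0.03, -0.23 and 0.06.

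Genes that passed in all 3 treatments in the same direction addressed what the treatments had in common. Of 649 genes that passed in all 3 in any direction, 144 had the same direction throughout, 40 higher and 104 lower. Most of the 649 thus did not move the same way in all 3. Car3 fell in CI, TNF and DEX by 0.68, 1.45 and 3.87, Mettl7b by 0.86, 0.69 and 1.31, Greb1 by 0.89, 0.75 and 0.88, and Amy1 by 0.87, 1.10 and 0.87. Vnn3 (-0.63, -0.75 and -1.32), Tinag (-0.59, -0.57 and -0.87) and Tfrc (-0.56, -0.68 and -0.57), which encodes the transferrin receptor, were lower in each as well. Lcn2 rose by 1.69, 4.63 and 2.49, and Mpp6 by 0.85, 0.36 and 0.54. The other 6 of the 8 largest shared increases (Olr1, Ets2, Lrwd1, Fosl1, Erdr1 and Trim47), and Osr2 among the decreases, did not pass in CI without CI replicate 1 (adjusted p from 0.0827 for Erdr1 to 0.415 for Lrwd1), and all of these but Osr2 failed in CI under other alternatives as well. In DEX, Fosl1 did not pass under 9 alternatives (adjusted p from 0.0536 to 0.189), among them leaving out control replicate 1 or 2, TNF replicate 1, or DEX replicate 1 or 2. Olr1 did not pass in DEX under 4 (0.0506 to 0.0838), with trend and robust and without control replicate 1 or 2 or DEX replicate 2. Erdr1 did not pass in TNF without control replicate 3, TNF replicate 1 or TNF replicate 2 (0.0553 to 0.0800). Independent lists of these sizes would share 25.4 genes higher and 21.1 lower, and simulated unchanged groups with shared simulated controls shared 0 in 100 draws. No expected number was computed for the 649 genes that passed in any direction. The excess may thus lie in passing together rather than in a shared direction. Part of the excess of the 144 may also come from the shared controls. The count was 87 without control replicate 1, 79 without control replicate 2 and 77 without CI replicate 1. Without CI replicate 1 the remaining CI sample is assumed to vary like the other groups.

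TNF and DEX shared 1309 calls in the same direction, 694 higher and 615 lower, where independent lists would share 303 and 239, and 508 calls were opposite, where 540 would be. CI and TNF shared 418 calls in the same direction (182 and 155 for independent lists, observed 196 and 222) and had 700 opposite calls (339 for independent lists). CI and DEX shared 505 in the same direction (183 and 188 for independent lists, observed 160 and 345) and had 795 opposite calls (371 for independent lists). Simulated unchanged groups shared on average 0, 18.5 and 0.04 calls in the same direction for TNF and DEX, CI and TNF, and CI and DEX. The highest of the 100 draws gave 0, 1848 and 4, so for CI and TNF a draw with no effect exceeded the observed 418. A draw can hold copies of an array's deviation, which the real arrays do not. Copies lower the spread and can raise the calls, and whether they did so in that draw was not checked. The controls could not be split into parts of at least 2 arrays, so part of the excess of same-direction calls may come from the shared controls. The covariance of log2 fold changes over genes was 0.0165 for TNF and DEX (simulated 0.00247, SD 0.00223, difference 0.0140). It was -0.00506 for CI and TNF (simulated 0.00236, SD 0.00275, difference -0.00742) and -0.00558 for CI and DEX (simulated 0.00259, SD 0.00289, difference -0.00817). Without control replicate 3 the value for CI and DEX was -0.00234. The correlations over genes, which are not independent replicates, were 0.208, -0.103 and -0.0905. The simulated values spread widely, with means of 0.436 (SD 0.306), 0.344 (SD 0.356) and 0.386 (SD 0.394).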

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

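Of the tests in this part, those of the probe sets without a gene name and those of markers, scaling and single CI arrays that weigh the 3 patterns were chosen after the result was seen. Some gene lists passed the preset-correlation test in opposite directions in different treatments, and the difference was tested directly. Preadipocyte and fibroblast markers had a median of -0.19 in CI and 0.09 in TNF, a direct difference of 0.34 (adjusted p = 3.1e-05, and adjusted p = 0.169 with an estimated correlation). Interferon and MHC class I genes differed by -1.49 between DEX and CI (adjusted p = 3.87e-27, and adjusted p = 0.114 with an estimated correlation) and by 1.48 between TNF and DEX (adjusted p = 1.75e-32, and adjusted p = 0.0711 with an estimated correlation). Against control this list had small medians in CI (0.19) and TNF (0.09), and it did not pass there by fry (adjusted p = 0.212 and 0.0877) or with an estimated correlation (adjusted p = 0.935 and 0.541). Extracellular matrix genes differed by 0.47 between TNF and DEX (adjusted p = 8.52e-13, and adjusted p = 0.0711 with an estimated correlation), though in TNF against control the list did not pass with the dim filter at the median (adjusted p = 0.125), the mean of all probe sets (0.0734) or an estimated correlation (0.479). Probe sets without a gene name, which no comparison used, also differed: of 5951 tested, 110 were higher and 133 lower in CI, 313 and 351 in TNF, and 336 and 351 in DEX.

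In DEX, interferon and MHC class I genes fell together, with a median of -1.41. The cultures were of a cell line differentiated from preadipocytes, in which macrophages or other leukocytes would be contaminating cells. A loss of any such cells may lower interferon genes, and it would lower the abundant markers of those cells alike. The 9 markers brighter than the median probe set had a median of -0.10 and an interquartile range of -0.62 to -0.01. Of the 4 that passed, Mpeg1 (-1.67), Itgb2 (-0.96) and Lyz2 (-0.62) fell, Lyz2 and Mpeg1 being the 2 brightest in control, and Cd14 (0.90) rose. The 5 others lay at intensities of 132 to 445 in control, where the array medians were 125.8 to 129.5. Markers that move apart, some of them dim, do not exclude such a loss, and by fry the full list of 14 markers was lower (adjusted p = 0.000445). Quantile normalization left the list at -1.39 (camera, adjusted p = 1.05e-32). The deposited arrays had nearly equal quartiles, so this could move the list little and does not test the authors' own normalization. An effect of the glucocorticoid itself, or of its carrier, stays open as a hypothesis. These arrays hold no test that parts the 2, and neither can be told apart from a loss of contaminating cells, if the cultures held any.

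In TNF, 114 genes of oxidative phosphorylation, the tricarboxylic acid cycle and branched-chain amino acid catabolism had a median of -0.28. Centring and quantile normalization left it at -0.26 and -0.29. As the deposited quartiles differed by at most 0.0763, these could move it little and do not test the authors' own normalization. Of 10000 random lists matched on expression 0 had a median as low (their range was -0.07 to 0.08), so brightness does not account for it. A lower share of adipocytes may lower these genes and raise the markers of preadipocytes, whose median was 0.0917 with an interquartile range of -0.10 to 0.60. As 7 of these markers rose and 1 fell, a change in the cells' composition and a change within adipocytes cannot be told apart here.

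CI and TNF shared 418 calls in the same direction and had 700 opposite ones. After quantile normalization the opposite calls were 747 against 438. For arrays with nearly equal quartiles this is a small change, so it does not test the scaling that the authors used. Without CI replicate 2 they were 516 against 290, and without CI replicate 1 they were 440 against 222, which argues against a single array. In both fits the remaining CI sample is assumed to vary like the other groups. Compared directly, the arrays of the 2 treatments differed in 5651 genes. Whether the treatments or other differences between the samples caused the opposite calls was not tested.

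The 10 ways to split 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 3924 genes in TNF, 4310 in DEX and 5636 between TNF and DEX, each 1 of 10, and the highest of the other splits gave 0. For lists past the preset-correlation test, 2 of 10 splits gave as many in TNF (real 15, highest other 16), 4 in DEX (real 8, highest other 10) and 1 between TNF and DEX (real 15, highest other 12). Each other split sets arrays of both groups against each other in unequal numbers, so it keeps part of the real difference. The mixed sets also carry the real difference in their spread, which lowers the number of genes called. The 0 genes of the other splits were thus largely fixed in advance.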

How the results depend on the processing

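No alternative reported here was chosen after the result was seen. Across 10 alternatives other than leaving out an array, the numbers of genes called stayed within 1.5 times in all 6 comparisons (2424 to 2871 in CI, 3626 to 4232 in TNF, 3931 to 4408 in DEX). Of 359 calls of named genes, 312 were kept under every alternative that gave a value, and 23 of the 359 had none under at least 1 alternative, mostly the dim filter at the median. Most named genes were chosen for large changes or small adjusted p-values, which favours keeping their calls. Of all genes called in CI, TNF and DEX, 75.1%, 79.6% and 82.5% were called again with the mean of all probe sets. Without control replicate 2 these shares were 70.4%, 70.4% and 78.3%, and in CI they were lower where 1 CI array was left. Lss in CI turned from 0.30 to -0.059 (adjusted p = 0.645) with the mean of all probe sets, and another of its probe sets was called in the opposite direction. With that mean, 35, 21 and 34 called genes changed sign in CI, TNF and DEX. With an estimated correlation 0 lists passed in each treatment. The covariance of CI and TNF was -0.00709, of CI and DEX -0.00865 and of TNF and DEX 0.0201 with the dim filter at the median, which tests fewer genes, and that of TNF and DEX was 0.0131 with the mean of all probe sets. Leaving out each array gave 1431 to 3043 genes in CI, 77 to 147 genes in all 3 treatments, 5 to 8 lists in CI, and covariances of -0.00618 to -0.00344 for CI and TNF, -0.00683 to -0.00234 for CI and DEX and 0.0156 to 0.0192 for TNF and DEX. The lowest CI count was without CI replicate 1, and the 8 lists were without CI replicate 2. For the covariances and lists the cause was not tested. Where 1 CI array is left, it is assumed to vary like the other groups.

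The replicate numbers did not establish a pairing: 6 of 15 same-number pairs had a correlation over 0.1 (-0.285 to 0.341), and 6 of 11 arrays lay closest to their own number. With the replicate number as a block 2786, 3974 and 4396 genes were called in CI, TNF and DEX and 5715, 5778 and 5284 between treatments, and 136 in all 3. The block changed no list call and ended 2 calls of named genes, Irs2 and Fosl1 in CI. Dim genes, under an intensity of 51.6, were left out unless the dim filter was dropped, which gave 2655, 4018 and 4372 called genes in CI, TNF and DEX.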

Other observations

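The lists in this part and their tests were chosen after the gene results were seen, and besides an estimated correlation and fry no alternative was run for these lists. Proteasome subunit genes rose in CI. Of 34 tested, 18 rose and 0 fell in CI (25 and 0 adjusted over the list alone, median 0.24, adjusted p = 5.82e-10, and adjusted p = 0.289 with an estimated correlation), including Psma1 (0.43) and Psmd6 (0.38). In TNF 8 fell and 0 rose (median -0.11, adjusted p = 0.000515, and adjusted p = 0.539 with an estimated correlation), and in DEX 8 fell and 1 rose (median -0.13, adjusted p = 0.00502, and adjusted p = 0.629 with an estimated correlation). By fry the list passed in CI (adjusted p = 0.0127) but not in TNF (0.0732) or DEX (0.113). Directly, 28 were lower in TNF than in CI (median -0.34, adjusted p = 2.77e-10, and adjusted p = 0.216 with an estimated correlation) and 26 lower in DEX than in CI (median -0.41, adjusted p = 2.73e-09, and adjusted p = 0.319 with an estimated correlation). Lysosome genes were lower in CI and higher in TNF by the preset-correlation test. Of 40 tested, 17 fell and 2 rose in CI (median -0.16, adjusted p = 1.33e-07, and adjusted p = 0.184 with an estimated correlation), including Glb1 (-0.80), and 16 rose and 0 fell in TNF (median 0.13, adjusted p = 4.75e-07, and adjusted p = 0.0817 with an estimated correlation), including Gla (0.96) and Ctsk (0.56). Between the treatments 27 were higher and 1 lower in TNF than in CI (median 0.31, adjusted p = 1.64e-11, and adjusted p = 0.0395 with an estimated correlation).

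Of 42 cytosolic ribosomal protein genes 21 rose and 0 fell in TNF (median 0.15, adjusted p = 8.49e-09, and adjusted p = 0.0817 with an estimated correlation) and 23 rose and 0 fell in DEX (median 0.16, adjusted p = 3.15e-07, and adjusted p = 0.224 with an estimated correlation), while the list did not pass in CI (adjusted p = 0.972). Of 21 acute phase and complement genes 14 rose and 3 fell in TNF (median 0.89, adjusted p = 1.33e-09, and adjusted p = 0.0450 with an estimated correlation), including Lbp (2.80), Hp (1.54) and Cp (1.43). The fixed lists also hold 6 of the 21. No genes already seen were taken out of this list, nor out of the proteasome, lysosome, ribosomal protein and clock lists. The tests of these lists thus do not stand apart from the gene results. In DEX the clock gene Dbp fell by 1.09 and Per1, a glucocorticoid receptor target, rose by 0.89. Of 10 clock genes of the arm that holds both, 5 fell and 1 rose (adjusted p = 0.0867), and of 5 clock genes of the opposite arm 3 rose and 0 fell (adjusted p = 0.0324, and adjusted p = 0.224 with an estimated correlation), including Nfil3 (0.61), Cry1 (0.40) and Arntl (0.39).

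A hypothesis for the higher Dusp4 and Dusp6 in CI is that ERK feedback genes are higher together. The 17 other members tested had a median of 0.0863, with 5 higher and 1 lower (adjusted p = 0.234), so the list did not pass and the question stays open. The same members passed by the preset correlation in TNF, where 8 rose and 1 fell (median 0.23, adjusted p = 0.0189, adjusted p = 0.0559 by fry, and adjusted p = 0.539 with an estimated correlation), though the list did not pass between TNF and CI (median 0.07, adjusted p = 0.518). A hypothesis for the higher Cth and Chac1 in CI is that genes of the amino acid response are higher together. The 27 other members tested had a median of 0.22, with 13 higher and 1 lower (adjusted p = 1.34e-06, adjusted p = 0.00508 by fry, and adjusted p = 0.229 with an estimated correlation), which is consistent with it by the first 2 tests, while the third did not pass. The fixed lists hold 5 of the 27, and the 22 others had a median of 0.22 as well. Chac1 (0.76) did not pass without CI replicate 1 (adjusted p = 0.0594), where the other CI sample is assumed to vary like the other groups.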
